A study of Arabidopsis thaliana with 26 samples.

How the data were processed

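RNA from Arabidopsis thaliana (background Columbia-0, per the labels) was measured on 26 Affymetrix ATH1 arrays, a 1-colour format in which biotin-labelled cRNA from 1 sample is hybridised to each array. Per the labels' protocols, RNA was extracted with a column kit, and 18 plants were pooled for each sample. The deposited values are probe set intensities on a linear scale, 1 value for each of 22810 probe sets on each array. Per the deposited intensity values, every array has been scaled by the authors to the same level: the mean after trimming 2% at each end was 100.01 on all 26 arrays. The software and summary method behind the intensity values are not given in the sources used here. No value was missing or negative, 581 values were 0, and the highest was 4480.8. Array medians lay between 38.2 and 44.4, and array maxima between 3013.6 and 4480.8. The number of arrays limits the precision of every value below.

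Genes were named from the platform annotation of the probe sets. Of the 22810 probe sets, 64 of which are hybridisation or spike-in controls, 13513 are listed with 1 gene, 503 with several and 8794 with none. Of those with 1 gene, 13436 could be tied to a locus. No gene was named from a probe set with several genes, and a probe set listed without a gene is given by its identifier. None of the 3 mutated genes (SFR2, SFR3 and SFR6) has a probe set named in this annotation, so their own transcripts were not analysed here and give no check of the genotype labels.

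Groups and replicate numbers were taken from the labels. There were 2 arrays in each of 13 groups: 8 groups from wild type (wt) and the mutant lines labelled sf6, sf3 and sf2, each with and without 24 h at 4 °C, 2 groups of wt and sf6 dried for 2 h, and 3 groups coded 00f, 03f and 24f, for which the labels give no genotype and no meaning of the code. The last 3 groups were grown in another regime and were tested only against each other, 1 alternative fit held all 26 arrays, and where their levels or changes are set beside those of wt no test was made. Nothing in the labels says that the 2 arrays of a group come from separate cultures or sowings, so the p-values measure the spread between these samples, which may be technical. Replicate arrays correlated at 0.983 to 0.9918 across probe sets (log2 scale), and no pair of arrays held identical values. Replicates were often not the closest arrays. Each cold array of wt, sf6 and sf3 was closest to a cold array of another line, and each sf2 control array to an sf6 control array. Wt cold replicate 2, for example, correlated with sf6 cold replicate 1 at 0.9887, against 0.9869 with its own replicate. Wt control replicate 1 correlated with sf2 control replicate 1 at 0.9903, against 0.9887 with its own replicate. The sf3 control replicates 1 and 2 were closest to wt control replicates 1 and 2 (0.9878 and 0.9865), against 0.983 with each other.

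From the deposited intensity values, log2(intensity + 16) was computed and tested with limma 3.58.1 in R 4.3.3 (linear model on groups, moderated test with an intensity trend, no replicate block). A fold change is therefore on the log2(intensity + 16) scale, which understates changes of dim genes. Control probe sets, and probe sets whose mean over the arrays of the fit lay below the 25th percentile, were left out, which left 17059 probe sets in each fit. The 20 arrays of the first 10 groups entered 1 fit with 10 residual degrees of freedom (6.58 prior degrees of freedom), and the 6 arrays of 00f, 03f and 24f another with 3 (7.52 prior). P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05, over the probe sets of each of 16 comparisons. At an unadjusted p under 0.05, chance alone would give 853 probe sets per comparison. SE is the standard error of the fitted log2 change. SD is over the 2 arrays of a group on the intensity scale.

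The genes named in the text follow a rule fixed before the data were examined. It takes the mutated genes first. It then takes, per comparison, the 5 genes with the largest rise and the 5 with the largest fall among those past the threshold whose compared groups do not overlap. For a difference of responses, all treated-minus-control differences of the mutant must lie on 1 side of those of wt. Finally it takes, per gene list discussed, up to 4 members with the smallest adjusted p and any member that went the other way past the threshold. Where several probe sets name a gene, the one with the highest mean was used. Genes named outside the rule are marked where they appear.

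Before the data were examined, 20 gene lists with 275 genes were fixed, but only 31 of those genes have a named probe set here and 6 of the lists have none. For that reason 26 further lists (382 genes) were written from the annotation, before any comparison was computed. They share members with the first lists, so their results are not separate evidence. Member counts of all lists below cover only the genes tested here, not the whole lists. Lists with at least 3 tested members (31 per comparison) were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists of a comparison. The lists described in the text were chosen after the list results were seen. A set of cold-responsive probe sets was chosen on sf2 and sf3 arrays alone, so that wt and sf6 could be compared on it.

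The test was checked on simulated data with the spread of the real arrays and 200 changed genes in each of 10 draws, over 17059 probe sets. For the cold response in wt it recovered 35.2% of changes of 0.5, 94.6% of changes of 1 and 100% of changes of 2 (log2). For the comparison of sf6 with wt in control plants the shares were 39.8%, 95.8% and 99.4%. For the difference of cold response between sf6 and wt they were 8.2%, 73.6% and 97.2%, and for the difference of drought response 8%, 76.6% and 96.6%. For 24f against 00f they were 34.4%, 97.8% and 99.2%. False calls made up 4.8%, 4.1%, 5.7%, 5.7% and 7.2% of the calls in these 5 comparisons. In the list test simulated for the cold response in wt, camera called 5 of 5 shifted lists and 0 of the others. The simulated probe sets varied independently of each other, so this check does not cover correlation between genes of a list. The comparisons of mutants with wt gave far fewer calls than 200. With so few changed genes the share recovered may be lower, which was not simulated.

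The alternatives were pseudocounts of 1 and 64, no filter on dim probe sets or the 50th percentile, quantile normalization, scaling to the array median, array quality weights, the replicate number as a block, fits with only the compared groups or with all arrays, a 2-fold minimum, leaving out each array in turn, and leaving out the 2 arrays whose titles end in a repeat mark. Comparing each mutant with the mean of the other mutants, and averaging genotypes over treatments, were added after the data had been seen. Figures were drawn with matplotlib 3.10.9.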

Results

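Transcript levels were measured in the aerial tissue of Arabidopsis seedlings that had been grown on agar at 21 °C and 100% humidity in continuous light. Wild type (wt) was set beside 3 lines from a chemical mutagenesis, labelled sf6, sf3 and sf2, which the series title ties to the sensitive-to-freezing mutations sfr6, sfr3 and sfr2. Each line was sampled untreated (control) and after 24 h at 4 °C (cold). Wt and sf6 were also sampled after the aerial tissue had been cut off and dried in an air stream for 2 h (drought). Drought was compared with intact control plants, because there was no group that was cut and not dried. A further 3 groups, coded 00f, 03f and 24f, came from plants on compost at 4 °C and 70% humidity with 9 h of light and 15 h of dark, and carry no genotype. Every group had 2 arrays, each of 18 pooled plants, and every array was scaled to a trimmed mean intensity of 100.01. The titles of wt control replicate 1 and sf6 drought replicate 2 end in a repeat mark, and these are called the repeat1 arrays below. Over the first 20 arrays, the first principal component held 75.3% of the variance and set the cold arrays (-58.2 to -46.1) apart from all others (29 to 40.1). The second held 6.1% and set drought (14.9 to 26.7) apart from control (-15.8 to -1.9). Wt control replicate 2 (17.5) and sf3 control replicate 2 (26.5) stood apart from the other control arrays (-12 to 3.5) on the third component, which held 3.7%.

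The first question was how wild-type plants respond to cold. Cold-regulated genes were among the largest rises. COR15A, which encodes a small protein targeted to the chloroplast, went from 51.6 ± 4.7 in control to 3431.2 ± 183.7 in cold (SD, n = 2; log2 change 5.67, SE 0.16, limma adjusted p = 1.97e-13). The dehydrin gene LTI30 rose by 5.48 on the log2 scale (63.4 ± 11.6 to 3500.4 ± 156.7), and AT1G16850 rose most, by 5.90. AT1G51090 rose by 5.04, and LEA4-5, a late embryogenesis abundant protein gene, by 4.44. The falls were led by AT1G51400, from 2398.8 ± 22.2 to 105.6 ± 17.2 (log2 change -4.32, SE 0.19, limma adjusted p = 2.65e-11), then AT5G19120 (-4.08), AT5G14120 (-3.81), AT3G15450 (-3.79) and AT4G21870 (-3.75). In all, 8032 of 17059 probe sets (47.1%) passed an adjusted p of 0.05, 3539 higher and 4493 lower. At least a 2-fold change was met by 2064 of them, 951 higher and 1113 lower. The balance of directions depends on the scaling: with arrays scaled to their medians, 4521 were higher and 3407 lower, and the median change over all probe sets was 0.05 in place of -0.054.

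By gene group, all 4 measured members of the CBF regulon list (targets of the CBF transcription factors) rose in wt cold, also when adjusted over the list alone. COR47 rose by 3.12 and COR15B by 4.18, and the list's median change was 4.83 (camera adjusted p = 3.62e-06, and adjusted p = 0.00887 with an estimated correlation). All 6 measured members of the list of named cold-regulated and LEA proteins, which shares most members with it, rose too (median 4.31, camera adjusted p = 2.83e-07, adjusted p = 0.00736 with an estimated correlation). Of 15 dehydration and ABA-linked genes, 8 rose and 3 fell (median 0.40, camera adjusted p = 0.0169, adjusted p = 0.181 with an estimated correlation). RD2 rose by 2.00 on the log2 scale. The 3 that fell were DI19 (-1.85), the osmotin-like gene OSM34 (-1.29) and HIS1-3, a linker histone gene (-0.82). HIS1-3 lost its call without wt control replicate 2 (adjusted p = 0.334) or wt cold replicate 1 (adjusted p = 0.15), and with only the compared groups in the fit (0.0683).

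Of 23 nuclear photosynthesis genes, 19 fell and 1 rose in wt cold (median -0.56, camera adjusted p = 6.54e-05, adjusted p = 0.429 with an estimated correlation). LHCB4.2, an antenna protein gene of photosystem II, fell from 2664 ± 394 to 606.5 ± 115 (log2 change -2.11). The thioredoxin gene TRXF2 (-1.77), LPA2 (-1.49) and NdhL (-0.84) fell as well, while ATPC2 rose by 0.55 (call lost without wt control replicate 1, adjusted p = 0.0764, or both repeat1 arrays, 0.089). The longer photosynthesis list fixed beforehand had only 5 measured members. Of these 3 fell, or 4 adjusted over the list alone, and the camera adjusted p of the list was 0.108. Its other named members were PRK, the Calvin cycle kinase (-0.57, call lost without wt cold replicate 2 at adjusted p = 0.053), and LHCB4.1 (-0.32). LHCB4.1 kept no call under median scaling (-0.18, adjusted p = 0.245), with no filter on dim probe sets (0.0757), without both repeat1 arrays (0.129) or without any 1 of the 4 wt control and cold arrays, where its highest adjusted p was 0.138, without wt control replicate 1. Of 10 tetrapyrrole and chlorophyll genes, 6 fell (median -0.51, camera adjusted p = 0.0117, adjusted p = 0.488 with an estimated correlation), among them CHLM (-1.67), HEME1 (-1.45), HEMB1 (-0.65) and HEMA2 (-0.61).

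All 8 anthocyanin and flavonoid modification genes rose in wt cold (median 1.76, camera adjusted p = 6.27e-06, adjusted p = 0.121 with an estimated correlation). The flavonol glycosyltransferase gene UGT78D2 rose from 164.2 ± 1.5 to 856.7 ± 60.8 (log2 change 2.27), UGT78D3 by 2.1, CHIL by 2.06 and UGT78D1 by 1.11. The 3 measured members of the flavonoid synthesis list rose, also adjusted over the list alone, and camera gave an adjusted p of 0.0686. AT4G14090 rose by 1.91, UF3GT by 1.61 and DFR, the dihydroflavonol reductase gene, by 0.71. The call of DFR ended without wt cold replicate 1 (adjusted p = 0.192), wt control replicate 2 (adjusted p = 0.125) or both repeat1 arrays (0.0599). Of 17 RNA polymerase and ribosome biogenesis genes, 11 rose (median 0.57, camera adjusted p = 3.62e-06, adjusted p = 0.102 with an estimated correlation), including NRPA1, the largest subunit of RNA polymerase I (1.42), YAO (1.4), NRPB12 (1.33) and IMP4 (1.16). In the list of tricarboxylic acid cycle and cytochrome c genes 7 of 10 rose and 2 fell (median 0.51, camera adjusted p = 0.0419, adjusted p = 0.181 with an estimated correlation). CYTC-2 (1.55), SDH1-1 (1.27) and MDH (0.57) rose, and the isocitrate dehydrogenase genes cICDH (-1.17) and ICDH (-0.37) fell. ICDH kept no call under median scaling (-0.26, adjusted p = 0.11), under quantile normalization (0.106) or with only the compared groups in the fit (0.055), nor without wt control replicate 2 (adjusted p = 0.19), wt cold replicate 1 (0.0925) or wt cold replicate 2 (0.0868). Autophagy genes went down: 9 of 10 members of the ATG8 and ATG3 list fell (median -0.49, camera adjusted p = 0.00137, adjusted p = 0.356 with an estimated correlation), among them ATG8E (-3.24), ATG8F (-2.11), ATG8C (-0.99) and APG8H (-0.53). PYK10, a glucosidase gene of roots and hypocotyls chosen from the root markers after its values were seen, fell from 1619.4 in control to 913.5 in cold (log2 change -0.82, SE 0.12), so the share of such tissue in the samples is open.

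**Figure D1:**
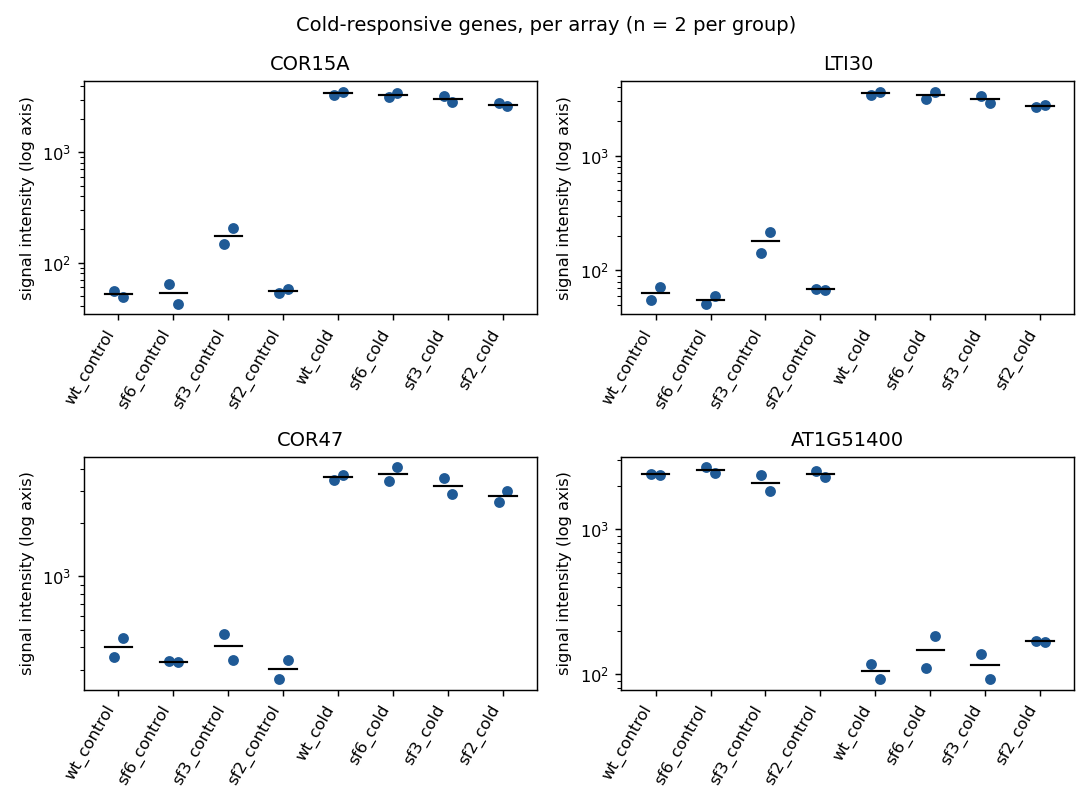
Signal intensity (log axis) of COR15A, LTI30, COR47 and AT1G51400 on each array of the 4 lines in control and cold, with points for arrays and lines for group means (n = 2). COR15A lies near 51.6 to 55.2 in control wt, sf6 and sf2, at 175.8 in control sf3, and between 2707.9 and 3431.2 in the 4 cold groups.

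The next question was whether the cold response is kept in the mutants. In sf6 the same cold genes rose: COR15A went from 53.2 ± 15.4 to 3321.1 ± 172.3 (SD, n = 2; log2 change 5.61, SE 0.16, limma adjusted p = 2.37e-13). LTI30 rose by 5.56, COR15B by 4.26 and COR47 by 3.42. The largest rise was that of AT1G16850 (5.74), and AT1G51090 rose by 5.06 and AT1G11210 by 4.38. The largest falls in sf6 were AT1G51400 (-4.03), the expansin gene EXPA8 (-3.92), AT2G34620 (-3.82), AT4G33666 (-3.57) and AT5G14120 (-3.56). In sf6 cold, 7744 probe sets passed the threshold, 3334 higher and 4410 lower (4123 and 3392 under median scaling). Of 7 glucosinolate metabolism genes 6 fell in sf6, among them the transporter genes GTR1 (-0.73) and GTR2 (-0.77), AOP1 (-0.69) and BCAT4 (-0.72). That list had a median of -0.69 (camera adjusted p = 0.0117, adjusted p = 0.188 with an estimated correlation). None of these named genes was called in the difference of cold response between sf6 and wt, so the fall is not shown to be particular to sf6.

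In sf3, 7534 probe sets passed in the cold, 3412 higher and 4122 lower (4244 and 3272 under median scaling), and in sf2 7285 passed, 3377 higher and 3908 lower (3718 and 3444 under median scaling). AT1G51090 led in sf3 with 4.83, followed by AT1G16850 (4.79), AT2G16890 (4.2), COR15A (4.03) and LTI30 (4.01). AT1G51400 (-4.03), AT3G15450 (-3.53), AT5G14120 (-3.49), AT1G62480 (-3.47) and AT1G23390 (-3.42) fell most. In sf2 the largest rises were AT1G16850 (5.64), COR15A (5.26), LTI30 (5.02), AT1G51090 (4.60) and AT1G11210 (3.96). The largest falls there were EXPA8 (-3.97), AT1G51400 (-3.71), AT5G44020 (-3.39), AT1G62480 (-3.34) and AT5G14120 (-3.23). All 4 measured members of the CBF regulon list rose in each mutant, also adjusted over the list alone. Its median change was 4.91 in sf6, 3.98 in sf3 and 4.48 in sf2, with adjusted p values of 0.00661, 0.0107 and 0.00737 with an estimated correlation.

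On probe sets chosen in sf2 and sf3 alone, wt and sf6 could be compared without favouring wt. The 678 probe sets raised in both had a median cold response of 1.55 in wt and 1.56 in sf6, and the median difference of sf6 minus wt was -0.03 (bootstrap interval -0.05 to 0.00). The 672 lowered in both had medians of -1.65 and -1.51, with a median difference of 0.12 (0.09 to 0.15). Bootstrap intervals here and below resample probe sets, not arrays. Over the 2 cold arrays the median of the lowered set had an SD of 0.1 in wt and 0.065 in sf6. A weaker fall in sf6 is therefore not shown. In the raised set 676 passed the threshold in sf6 and 674 in wt. Across 17059 probe sets the cold response of wt correlated with that of sf6, sf3 and sf2 at r = 0.91, 0.93 and 0.91 (Spearman 0.85, 0.88 and 0.84). These comparisons share no arrays, and probe sets are not independent replicates. Of the 951 probe sets raised at least 2-fold in wt, 925 were called higher in sf6, against 185.9 for independent lists.

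**Figure D2:**
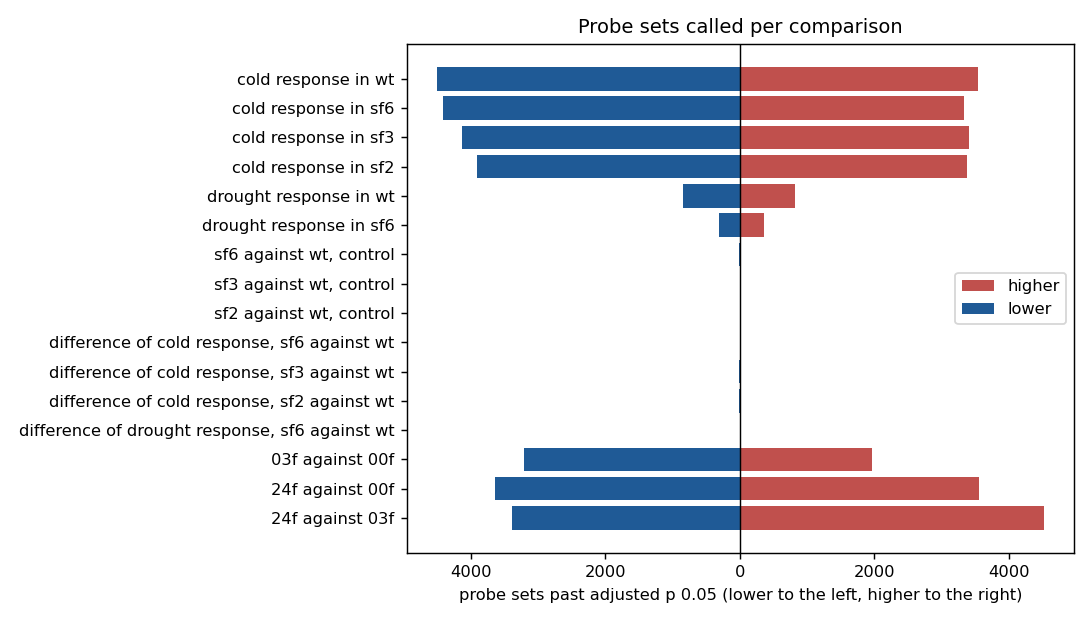
Number of probe sets past an adjusted p of 0.05 in each of the 16 comparisons, with bars to the right for higher and to the left for lower. The cold responses reach 7285 to 8032 calls in total, the drought responses 667 and 1670, and the comparisons of mutants with wt 0 to 22.

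The difference of cold response between each mutant and wt was tested directly. For sf6 only 6 probe sets passed, 5 higher and 1 lower, at 1867 below an unadjusted p of 0.05. AT4G01870 rose more in sf6 than in wt (difference 2.33, SE 0.29, limma adjusted p = 0.006), going from 85.8 ± 22.1 to 1321.3 ± 261.1 in sf6 and from 251.7 to 668.2 in wt (n = 2). AT1G52200 differed by 1.65, AT1G33600 by 1.02, and DME, a DNA demethylase gene, by 1.36. AT3G09440, a cytosolic Hsp70 gene, differed by -1.18. DME fell in the cold in sf6 (51.7 ± 7.5 to 28.1 ± 5.3), by less than in wt. In control plants AT3G09440 was higher in sf6 than in wt (log2 change 1.00) and AT4G01870 was lower (-1.37, wt control SD 89.7). Part of the differences of these genes in response therefore lay in the control levels. The 5 named genes include no COR gene, and the 4 measured members of the CBF regulon list had a median difference of 0.08 (camera adjusted p = 0.7). The 3 flavonoid synthesis genes had a median difference of -1.02, with 0 past the threshold by limma and 3 lower adjusted over the list alone (camera adjusted p = 0.00336, adjusted p = 0.333 with an estimated correlation). The 6 calls moved with single arrays: leaving out sf6 control replicate 2 left 0 calls by limma (highest adjusted p of the 5 named genes 0.157), leaving out wt control replicate 2 left 1 (4 of the 5 lost, highest 0.181) and leaving out sf6 cold replicate 2 gave 3, of which 2 were among the 6 (3 lost, highest 0.0881). Without sf6 control replicate 1, 2 of the 5 lost the call (highest 0.127). Leaving out wt control replicate 1 gave 54 calls, wt cold replicate 2 44 (21 higher and 23 lower), sf6 cold replicate 1 21 (1 lost, 0.064) and wt cold replicate 1 10. Other choices ended them too: all 5 named genes lost the call with no filter on dim probe sets (0.0522 to 0.0903), with only the compared groups in the fit (0.134 to 0.234) and against the mean of the other mutants (0.445 to 0.98), AT1G52200 and AT1G33600 did so under median scaling (0.0506 each), and DME at a pseudocount of 64, where it differed by 0.55 (0.0815).

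For sf3, 7 probe sets passed in the difference of cold response, 2 higher and 5 lower. COR15A differed by -1.64 (SE 0.23, limma adjusted p = 0.0181), AT5G59330 by -1.55, AT1G57590 by -1.53 and DME by 1.2. The CBF regulon list had 1 of 4 members lower, or 2 adjusted over the list alone, with a median of -0.85 (camera adjusted p = 5.84e-05, adjusted p = 0.0215 with an estimated correlation). The sf3 cold level of COR15A was 3083.2 ± 277.6, so the smaller response went with a higher control level (175.8 ± 40.4 against 51.6 ± 4.7 in wt). Without wt control replicate 1 there was 1 call, which was not among the 7, without sf3 control replicate 1 there were 19, and each of the 4 named genes lost its call without wt control replicate 1 (highest adjusted p 0.138), wt control replicate 2 (3 calls, 1 of them among the 7, 0.188) or wt cold replicate 2 (3 calls, 1 among the 7, 0.123). Without sf3 cold replicate 1 there were 4 calls, 2 of them among the 7, and 3 of the 4 genes lost theirs (highest 0.157), and 2 did without sf3 control replicate 1 (0.076), sf3 control replicate 2 (0.121) or wt cold replicate 1 (0.135). All 4 also lost the call with array quality weights (COR15A 0.0927, highest 0.114), with only the compared groups in the fit (COR15A 0.163, highest 0.44) and without both repeat1 arrays (COR15A 0.0857, highest 0.189). AT5G59330, AT1G57590 and DME lost it with the replicate block (0.06 to 0.0626) and with no filter on dim probe sets (0.0817 to 0.0876), AT5G59330 at a pseudocount of 1 (-3.11, 0.0976), under quantile normalization (0.0956) and against the mean of the other mutants (-1.03, 0.114), DME in that comparison too (0.01, 0.992), and AT1G57590 (-0.92, 0.0947) and DME (0.48, 0.176) at a pseudocount of 64.

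For sf2, 22 probe sets passed, 9 higher and 13 lower (10 and 25 under median scaling), among them AT4G01870 (2.22), AT1G52200 (1.64), AT1G32460 (0.96) and AT1G63880 (0.84). The lower ones included AT2G15020 (-1.78), AT5G05220 (-1.46), AT3G09440 (-1.30), AT5G02230 (-1.0) and AT1G06000, a flavonol rhamnosyltransferase gene (-1.0). Part of this lay in the control levels. AT2G15020, AT3G09440 and AT5G02230 were higher in sf2 control than in wt control (1.23, 1.12 and 0.79). No member of the CBF regulon list passed (median -0.33, camera adjusted p = 0.258). Leaving out sf2 cold replicate 1 left 3 calls, with 7 of the 9 named genes no longer called (highest adjusted p 0.186), and leaving out wt control replicate 1 gave 54, 32 higher and 22 lower (1 lost, 0.0703). The count was 4 without wt control replicate 2 (6 lost, highest 0.244), 5 without sf2 cold replicate 2 (6 lost, 0.135), and 6 without sf2 control replicate 1 (5 lost, 0.178), sf2 control replicate 2 (5 lost, 0.104) or wt cold replicate 2 (6 lost, 0.108). Without wt cold replicate 1 there were 31, 23 higher and 8 lower, and 4 of the 9 lost the call (0.104), so the balance of directions turns with single arrays. With no filter on dim probe sets 5 of the 9 lost the call (0.065 to 0.0936), with only the compared groups in the fit 4 of the 8 tested there (0.0663 to 0.109), without both repeat1 arrays 2 (0.0676 each) and against the mean of the other mutants all 9 (0.301 to 0.985). At a pseudocount of 64 AT1G32460 (0.76, 0.0628) and AT5G05220 (-0.55, 0.0642) lost it, as did AT5G05220 with array quality weights (0.0506) and AT1G06000 under quantile normalization (0.0809). The 3 differences share the wt arrays, and 5 probe sets passed in at least 2 mutants. Over 50 simulated data sets without effects the mean was 0.04 and the maximum 1. Without effects hardly any probe set is called, so a low overlap there was fixed in advance. How much of the observed overlap comes from the shared arrays cannot be told from it.

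Untreated mutants were next set beside untreated wt. Sf6 control differed from wt control at 5 probe sets, 1 higher and 4 lower, with 1821 below an unadjusted p of 0.05. AT3G09440 was higher (773.8 ± 105.6 against 376 ± 5.9, SD, n = 2; log2 change 1.00, limma adjusted p = 0.00352). AT4G01870 (-1.37), AT5G39580, a peroxidase gene (-1.34), and AT2G05540 (-1.21) were lower, as was the unnamed probe set 261639_at, which was chosen after its values were seen. The CBF regulon list had no member past the threshold (median -0.17, camera adjusted p = 0.501). Without wt control replicate 2 the count was 1, and without wt control replicate 1 it was 107. The 4 named genes all lost the call without wt control replicate 2 (highest adjusted p 0.38) or sf6 control replicate 2 (2 calls, 1 of them among the 5, highest 0.449), and AT5G39580 without sf6 control replicate 1 (0.105). AT4G01870, AT5G39580 and AT2G05540 also lost it with no filter on dim probe sets (0.127 each) and with only the compared groups in the fit (0.0871 to 0.125), AT5G39580 (0.0519) and AT2G05540 (0.0627) at a pseudocount of 1, and AT2G05540 under median scaling (0.0627) and with the replicate block (0.0604). Against the mean of the other mutants AT3G09440 (0.00, adjusted p = 0.998), AT5G39580 (-0.66, 0.316) and AT2G05540 (-0.88, 0.0973) were not called.

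In sf3 control, 20 probe sets were higher than in wt and 1 was lower. Cold-regulated genes were among them: COR15A stood at 175.8 ± 40.4 against 51.6 ± 4.7 (SD, n = 2; log2 change 1.49, SE 0.16, limma adjusted p = 0.000444) and LTI30 at 179.4 ± 52.4 against 63.4 ± 11.6 (log2 change 1.28). AT2G37870 was higher by 1.86, AT4G33550 by 1.78 and AT1G57590 by 1.22. The CBF regulon list had 2 of 4 members higher, also adjusted over the list alone (median 0.67, camera adjusted p = 1.23e-05, adjusted p = 0.0113 with an estimated correlation). The overlapping list of named cold-regulated and LEA proteins had 2 of 6 higher (median 0.61, camera adjusted p = 1.23e-05, adjusted p = 0.0113 with an estimated correlation). Of 15 dehydration and ABA-linked genes 1, LTI30, was higher (median 0.10, camera adjusted p = 0.000182, adjusted p = 0.049 with an estimated correlation). Sf3 control replicate 2 and wt control replicate 2 stood apart on the third principal component, and with only the compared groups in the fit there were 3 calls, 2 of them among the 21, and all 5 named genes lost the call (adjusted p = 0.263 for COR15A, 0.662 for LTI30, 0.989 at most). Without both repeat1 arrays 4 of the 5 lost it (LTI30 0.0523, highest 0.265), and AT4G33550 did with no filter on dim probe sets (0.0729). Leaving out wt control replicate 1 gave 5 calls, 4 of them among the 21, and ended those of LTI30 (adjusted p = 0.129), AT2G37870 (0.0922), AT4G33550 (0.183) and AT1G57590 (0.0765). Leaving out wt control replicate 2 gave 11 and ended those of AT4G33550 (0.105) and AT1G57590 (0.0745). Leaving out sf3 control replicate 2 gave 12, 8 higher and 4 lower, of which 8 were among the 21, and ended the calls of LTI30 (0.0638) and AT4G33550 (0.0961), and leaving out sf3 control replicate 1 gave 50.

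Sf2 control differed from wt at 19 probe sets, 17 higher and 2 lower. AT2G15020 (1.23), AT3G14200 (1.2), AT3G09440 (1.12), AT1G60590 (0.97) and AT5G02230 (0.79) were higher, and AT5G39580 (-1.23) was lower. No member of the CBF regulon list passed (median 0.01, camera adjusted p = 0.74). Leaving out sf2 control replicate 2 left 0 calls by limma, with 1576 probe sets below an unadjusted p of 0.05 when all arrays were used, and leaving out wt control replicate 1 gave 91, 41 higher and 50 lower (59 without both repeat1 arrays, 23 higher and 36 lower). Without wt control replicate 2, 1 call was left and 5 of the 6 named genes lost theirs (highest adjusted p 0.628). AT3G14200 lost its call without wt control replicate 1 (0.0665), and AT1G60590 (0.118), AT5G02230 (0.0592) and AT5G39580 (0.153) without sf2 control replicate 1. With only the compared groups in the fit limma also gave 0 calls (0.11 to 0.183 for the 6 named genes), and all 6 lost the call against the mean of the other mutants (0.0665 to 0.999). With no filter on dim probe sets AT3G14200, AT1G60590, AT5G02230 and AT5G39580 lost it (0.0639 to 0.109), AT3G14200 did at a pseudocount of 64, where it differed by 0.51 (0.213), and without both repeat1 arrays (0.0938), and AT1G60590 under median scaling (0.0513) and with the replicate block (0.0527). AT5G39580, AT3G09440 and 261639_at were called in at least 2 mutants against the shared wt control arrays. The 50 simulated data sets without effects gave 0 at most, which was fixed in advance because hardly any probe set is called in them. Part of the observed overlap may come from the shared arrays.

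The response to drying was the next comparison. Drying here and below stands for cutting and drying together, which cannot be told apart against intact controls. In wt, STZ, a zinc finger repressor gene, rose from 62.4 ± 17.3 to 937.7 ± 53.7 (SD, n = 2; log2 change 3.62, SE 0.24, limma adjusted p = 1.61e-07). AT4G27280 rose by 2.91, AT1G72920 by 2.69, AT3G10930 by 2.53 and ORA47, an AP2/ERF regulator gene, by 2.50. AT2G30600 (-1.77), the expansin-like gene EXLA1 (-1.61), AT1G50040 (-1.58), AT1G62500 (-1.37) and AT1G10980 (-1.27) fell. In all 1670 probe sets passed, 824 higher and 846 lower, and 218 changed at least 2-fold, 174 of them higher. Under median scaling 871 were higher and 639 lower. The count is sensitive to single arrays: it was 581 without wt drought replicate 1 (57.7% higher), 693 without wt drought replicate 2 (55.4%), 661 without wt control replicate 1 (58.5%) and 883 without wt control replicate 2 (56.1%). EXLA1 lost its call without any 1 of the 4 wt arrays, with a highest adjusted p of 0.0831 without wt drought replicate 1, and AT1G50040 did so without wt drought replicate 1 (adjusted p = 0.145) or wt control replicate 2 (adjusted p = 0.105).

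Of 8 U-box ubiquitin ligase genes 4 rose on drying in wt (median 0.52, camera adjusted p = 0.00126, adjusted p = 0.0604 with an estimated correlation): PUB19 (1.04), PUB23 (0.73), PUB24 (0.61) and PUB26 (0.59). Of 6 calmodulin-like genes 3 rose (median 0.39, camera adjusted p = 0.00326, adjusted p = 0.0734 with an estimated correlation): CML38 (1.51), CML23 (1.43) and CML43 (0.64). Among 11 jasmonate-linked genes ORA47, OPCL1 (0.75) and PDF1.4 (0.84) rose and THI2.2, a thionin gene, fell (-1.05), with a median of 0.28 (camera adjusted p = 0.0422, adjusted p = 0.134 with an estimated correlation). Of the CBF regulon list only COR15B rose past the threshold (148.8 ± 5.7 to 357.3 ± 58.5; log2 change 1.17), or all 4 adjusted over the list alone (median 0.46, camera adjusted p = 0.0134, adjusted p = 0.118 with an estimated correlation). In the dehydration and ABA-linked list 2 of 15 rose, PUB19 and XERICO (0.58), and the list was not called (median -0.02, camera adjusted p = 0.144). PUB23, PUB24, PUB26, CML43, PDF1.4, THI2.2, COR15B and XERICO each lost the call without wt drought replicate 1, with a highest adjusted p of 0.23 (COR15B), and 6 of the 22 named genes did so without wt control replicate 1 (highest 0.239, XERICO), 6 without wt control replicate 2 (highest 0.253, CML43) and 7 without wt drought replicate 2 (highest 0.13, THI2.2). Without both repeat1 arrays 8 lost it (0.0522 to 0.271), with no filter on dim probe sets COR15B (0.0834), THI2.2 (0.0704) and XERICO (0.0521) did, COR15B at a pseudocount of 1 (0.0512) and CML43 with only the compared groups in the fit (0.0631). PYK10 fell on drying in wt by 0.81 on the log2 scale (adjusted p = 0.000428).

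In sf6, STZ rose after cutting and drying from 44.3 ± 5.9 to 546.8 ± 24.3 (SD, n = 2, log2 change 3.23, limma adjusted p = 1.7e-06). AT4G29780 rose by 2.40, AT4G27280 by 2.26, AT3G10930 by 2.18 and ORA47 by 2.13. AT1G62500 (-1.90), AT2G33850 (-1.72), AT1G64450 (-1.20), AT5G58390 (-1.20) and the anthocyanin glycosyltransferase gene UF3GT (-1.18) fell. There were 667 calls, 363 higher and 304 lower, with 224 without sf6 control replicate 1 (69.6% higher), 140 without sf6 control replicate 2 (80%), 189 without sf6 drought replicate 1 (69.8%) and 226 without sf6 drought replicate 2 (61.9%). The 3 measured flavonoid synthesis genes fell, also adjusted over the list alone: AT4G14090 (-1.16), UF3GT and DFR (-1.01), with a median of -1.16 (camera adjusted p = 0.000897, adjusted p = 0.113 with an estimated correlation). The same 3 genes were the ones that fell among the 8 of the overlapping modification list (median -0.39, camera adjusted p = 0.000239, adjusted p = 0.113 with an estimated correlation). PUB19 (1.11) and PUB23 (0.69) rose, 2 of 8 U-box genes (median 0.30, camera adjusted p = 0.00236, adjusted p = 0.0719 with an estimated correlation). COR15B rose by 1.29, the only member of its list past the threshold, or 4 of 4 adjusted over the list alone (median 0.43, camera adjusted p = 0.00352, adjusted p = 0.0799 with an estimated correlation). AT4G14090, UF3GT, DFR, COR15B and PUB23 each lost the call without any 1 of the 4 sf6 control and drought arrays, with a highest adjusted p of 0.371 (UF3GT, without sf6 drought replicate 1). AT4G27280 (adjusted p = 0.0639) and PUB19 (0.0691) lost it without sf6 control replicate 2. The flavonoid calls also depended on other choices: at a pseudocount of 64 AT4G14090 fell by 0.55 (0.127) and UF3GT by 0.69 (0.0879), and with no filter on dim probe sets AT4G14090 (0.0596), UF3GT (0.0986) and DFR (0.0626) were not called, nor was COR15B (0.0928). UF3GT lost the call under median scaling (0.0587) and with the replicate block (0.0573), COR15B at a pseudocount of 1 (0.056), and AT4G14090, DFR, COR15B and PUB23 without both repeat1 arrays (0.154 to 0.173).

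The difference of drought response between sf6 and wt was called at 0 probe sets by limma, with 1098 below an unadjusted p of 0.05 against 853 by chance. STZ differed by -0.40 (SE 0.34, adjusted p = 0.893), and the CBF regulon list had a median difference of 0.02 (camera adjusted p = 0.951). The 69 plastid-encoded genes had a median difference of 0.30 with no member past the threshold (camera adjusted p = 3.24e-08, adjusted p = 0.736 with an estimated correlation). The larger number of calls in wt than in sf6 is therefore not shown to be a difference between the genotypes. Across probe sets the 2 drought responses correlated at r = 0.65 (Spearman 0.52), and 132 of the 174 probe sets raised at least 2-fold in wt were called higher in sf6, against 3.7 for independent lists. Drought in wt and cold in sf6, which share no arrays, correlated at 0.00 (Spearman -0.06). Their changed probe sets still overlapped, in both directions. Of 911 raised at least 2-fold in sf6 cold, 96 were called higher and 89 lower in wt drought, against 44 and 45.2 for independent lists. Of 934 lowered in sf6 cold, 90 were called lower and 97 higher, against 46.3 and 45.1.

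**Figure D3:**
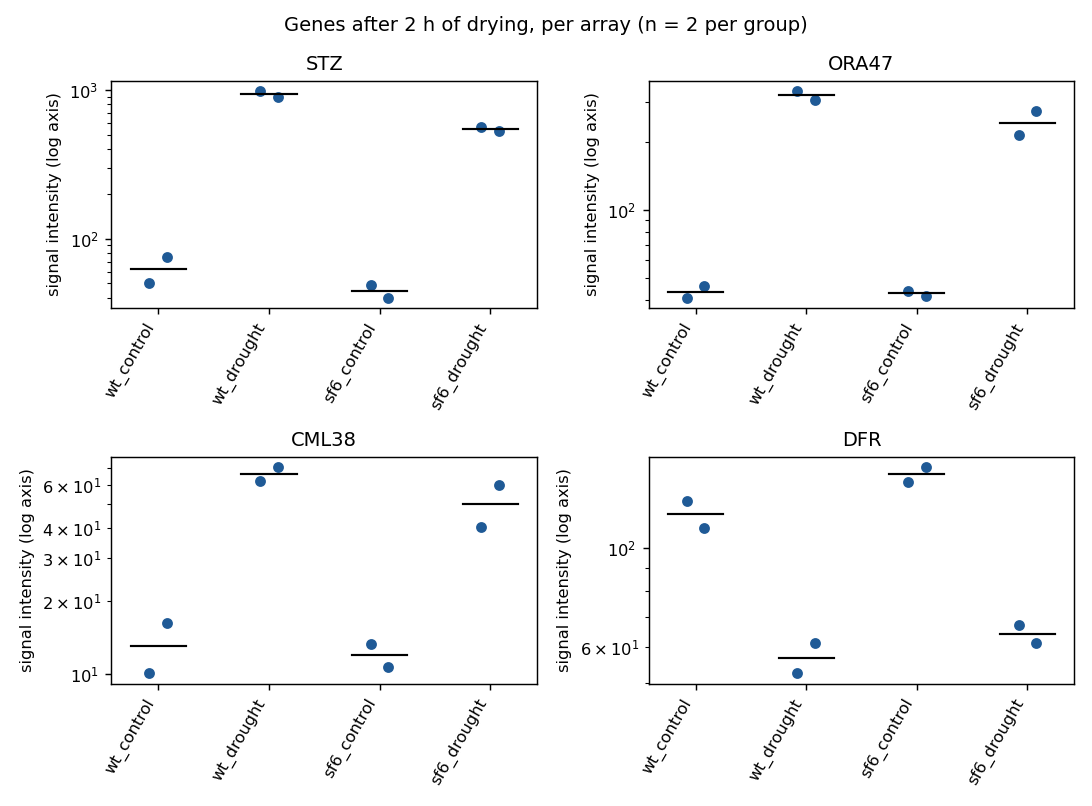
Signal intensity (log axis) of STZ, ORA47, CML38 and DFR on each array of wt and sf6 in control and drought, with points for arrays and lines for group means (n = 2). STZ lies at 62.4 and 44.3 in the control groups and at 937.7 and 546.8 after drying.

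The plants coded 00f, 03f and 24f were compared under their codes. In 03f, AT2G22880 stood at 537.1 ± 0.5 against 2 ± 0.2 in 00f (SD, n = 2; log2 change 4.95, SE 0.18, limma adjusted p = 2.68e-08). AT1G15010 was higher by 4.55, CML38 by 4.28, AT4G35985 by 4.25 and AT2G27080 by 4.19. AT3G15570 (-2.36), AT3G44450 (-2.36), AT1G07050 (-2.33), AT2G29670 (-2.09) and AT1G31920 (-2.09) were lower. In all 5171 probe sets passed, 1969 higher and 3202 lower, and the direction of the balance depended on scaling: with median scaling 2611 were higher and 1626 lower, and the median change over all probe sets was 0.008 in place of -0.132. Without 03f replicate 1 the count was 3100, and without 03f replicate 2 it was 3184.

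Of 7 calmodulin-like genes 3 were higher in 03f, CML38, CML37 (2.99) and CML23 (0.91), and CML41 was lower (-0.68), with a median of 0.25 (camera adjusted p = 0.0323, adjusted p = 0.569 with an estimated correlation). Of 8 U-box genes 4 were higher, PUB19 (2.27), PUB22 (2.09), PUB23 (2.05) and PUB43 (0.98), with a median of 0.56 (camera adjusted p = 0.00561, adjusted p = 0.569 with an estimated correlation). Of 23 nuclear photosynthesis genes 10 were lower (median -0.33, camera adjusted p = 0.0196, adjusted p = 0.569 with an estimated correlation), including LHCB4.2 (-0.92), NdhS (-0.85), CaS (-0.63) and PRK (-0.54). Of 7 flavonoid modification genes 4 were lower (median -0.72, camera adjusted p = 0.0323, adjusted p = 0.569 with an estimated correlation): UGT78D1 (-1.27), AT4G14090 (-1.16), UGT78D2 (-0.74) and AT5MAT (-0.72). CML23 lost its call without 03f replicate 1 (adjusted p = 0.29), 00f replicate 2 (0.182) or 00f replicate 1 (0.0721), and with no filter on dim probe sets (0.128). PRK lost its call under median scaling (-0.36, adjusted p = 0.117), with no filter on dim probe sets (0.0526) and without 03f replicate 2 (adjusted p = 0.218), 00f replicate 1 (0.126) or 03f replicate 1 (0.0631).

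In 24f, the defensin-like gene PDF1.4 stood at 1079.8 ± 97 against 24.7 ± 1.8 in 00f (SD, n = 2; log2 change 4.75, SE 0.13, limma adjusted p = 2.27e-08). AT4G27450 was higher by 4.33, AT2G05540 by 4.10, AT2G20670 by 3.87 and AT5G19120 by 3.67. The sucrose phosphate synthase gene ATSPS4F (-3.31), CHIL (-3.19), AT1G06000 (-3.17), AT3G44450 (-3.12) and AT4G14090 (-3.09) were lower. There were 7204 calls, 3561 higher and 3643 lower. All 10 ATG8 and ATG3 genes were higher (median 1.11, camera adjusted p = 1.18e-06, adjusted p = 0.488 with an estimated correlation), such as ATG8E (2.60), ATG8H (1.84), ATG8F (1.54) and APG8A (1.4). All 7 flavonoid modification genes were lower (median -1.77, camera adjusted p = 2.89e-06, adjusted p = 0.281 with an estimated correlation), with UGT78D1 at -2.16 and UGT78D2 at -1.77. The 3 flavonoid synthesis genes were lower too, also adjusted over the list alone, with DFR at -1.58 and UF3GT at -1.57 (median -1.58, camera adjusted p = 0.00517, adjusted p = 0.427 with an estimated correlation). Of 17 RNA polymerase and ribosome biogenesis genes 14 were lower (median -0.67, camera adjusted p = 1.77e-05, adjusted p = 0.281 with an estimated correlation), among them RH39 (-1.45), YAO (-1.32), NRPB12 (-1.20) and NRPA2 (-0.87).

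Between 24f and 03f, 7910 probe sets passed, 4525 higher and 3385 lower (3212 and 4484 under median scaling, with a median change over all probe sets of -0.046 in place of 0.086). AT2G20670 (4.82), PDF1.4 (4.39), AT4G27450 (4.19), AT2G05540 (3.81) and EXPA8 (3.81) were higher in 24f, and AT4G35985 (-3.92), AT1G51090 (-3.71), AT2G22880 (-3.58), AT2G17660 (-3.50) and CML38 (-3.42) were lower. All 4 measured CBF regulon genes were lower in 24f, also adjusted over the list alone (median -1.16, camera adjusted p = 0.00377, adjusted p = 0.417 with an estimated correlation). COR15B fell from 1807.4 ± 51.8 in 03f to 622.3 ± 9.6 in 24f (SD, n = 2), and the log2 changes of LTI30, COR47 and COR15A were -1.28, -1.04 and -0.91. Of 10 ATG8 and ATG3 genes 9 were higher (median 1.01, camera adjusted p = 0.000308, adjusted p = 0.574 with an estimated correlation), with ATG8E at 1.95, ATG8F at 1.72, APG8A at 1.19 and ATG8B at 1.09. Of 69 plastid-encoded genes 24 were higher (median 0.38, camera adjusted p = 0.00615, adjusted p = 0.721 with an estimated correlation), including psaC (1.31), ndhG (1.11) and psaA (1.02). AtpH differed by 1.56. In each of these named plastid genes the 24f arrays spread more than the 03f arrays. AtpH stood at 1069.6 ± 791.2 in 24f against 300.6 ± 43.9 in 03f, and psaC at 744.9 ± 341.7 against 275.6 ± 26.9. PsaA stood at 1936.2 ± 670.3 against 918.3 ± 13.4, and ndhG at 242.8 ± 64.5 against 102.9 ± 16.5.

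**Figure D4:**
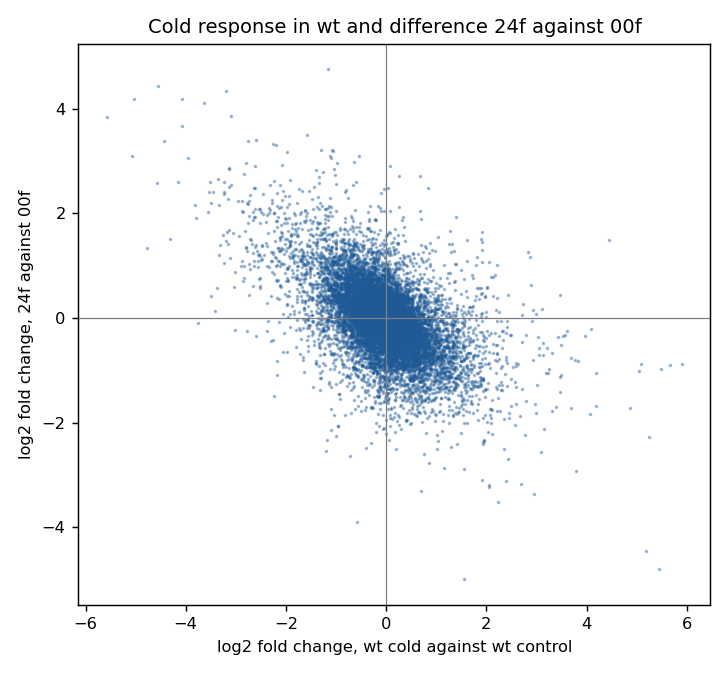
Log2 fold change of each probe set between 24f and 00f (vertical) against its log2 fold change in wt cold against wt control (horizontal). The 16432 probe sets tested in both run from upper left to lower right, with r = -0.55.

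Set beside the cold response of wt, the difference between 24f and 00f ran the other way: across 16432 probe sets r was -0.55 (Spearman -0.51), with no shared arrays. Of 926 probe sets raised at least 2-fold in wt cold, 647 were lower in 24f and 67 higher, against 201.9 and 193.9 for independent lists. Of 1052 lowered in wt cold, 750 were higher in 24f and 64 lower, against 220.3 and 229.3. ATG8E, ATG8F, UGT78D2, CHIL, YAO and NRPB12 were among the genes that went opposite ways. The difference between 03f and 00f correlated with the cold response of wt at 0.04 (Spearman 0.02). Of the 926 raised in wt cold, 195 were higher and 287 lower in 03f, against 103.1 and 177.4 for independent lists. Of the 1052 lowered, 358 were lower and 190 higher in 03f, against 201.5 and 117.1.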

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

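The tests on 261639_at and on genotypes averaged over treatments, on sf3 control replicate 1 alone, on probe sets with a low control level, and against the other mutants were chosen after the results were seen. A test of the difference of cold response between each mutant and wt singled out the genes below. In sf6 minus wt these were AT4G01870 (2.33), AT1G52200 (1.65), DME (1.36), AT1G33600 (1.02) and AT3G09440 (-1.18). In sf3 minus wt they were DME (1.2), COR15A (-1.64), AT5G59330 (-1.55) and AT1G57590 (-1.53), with the medians of the CBF regulon list (-0.85) and of the overlapping list of named cold-regulated and LEA proteins (-0.70). In sf2 minus wt they were AT4G01870 (2.22), AT1G52200 (1.64), AT1G32460 (0.96), AT1G63880 (0.84), AT2G15020 (-1.78), AT5G05220 (-1.46), AT3G09440 (-1.3), AT1G06000 (-1.0) and AT5G02230 (-1.0). With the other 2 mutants in place of wt, limma called 0 probe sets in the difference of cold response for sf6 and for sf2. With wt it called 6 and 22, and 1867 and 1865 lay below an unadjusted p of 0.05. For sf3 it called 5 with the other 2 mutants, of which 4 were among its 7 with wt.

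Arrays labelled sf6 showed a cold induction of COR genes close to that of wt, while sfr6 mutants are known for weak induction of such genes. If the arrays labelled sf6 held wt plants, no probe set would separate them from wt, but 261639_at, the only 1 of 17059 called and picked for that, differed by -1.71 over the 3 treatments (adjusted p = 8.52e-08), with all 6 arrays below all 6 wt arrays. A ceiling on bright signals would leave a weaker response visible in dimmer genes, if those genes share it. Over 498 raised probe sets with a wt cold mean under 500 the median difference of sf6 minus wt was 0.01 (bootstrap interval -0.04 to 0.04). It was -0.10 over 180 brighter ones. The COR genes were brighter than that bound (wt cold means 2981.2 to 3587.4), so a ceiling on their own signals was not tested and stays open. An exchange of sf6 with sf3 stays open: 261639_at was low in both (sf6 minus sf3 0.25, limma adjusted p = 0.423). COR15A had a smaller cold response in sf3 than in wt (-1.64), and the CBF regulon list had a median difference of -0.85. LTI30 rose by 5.48 in wt and 4.01 in sf3, but COR47 (3.12 and 2.95) and COR15B (4.18 and 3.95) rose nearly as much in sf3. The smaller responses of COR15A and LTI30 went with higher control levels. The sf3 cold levels of COR15A (3083.2), LTI30 (3091.6), COR47 (3223.3) and COR15B (2617.1) were close to those of wt (3431.2, 3500.4, 3587.4 and 2981.2). A response of this allele at 24 h of cold and a mislabelling with plants outside the series also stay open and were not tested.

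Cold-regulated genes such as COR15A and LTI30 were higher in sf3 control than in wt control. Over the 50 probe sets with the largest cold rise in sf2 and sf6, the median share of that rise present in replicate 1 alone was 5.61% (bootstrap interval 3.49 to 8.34). In replicate 2 it was 2.49%. In the 4 sf6 and sf2 control arrays it was 0.769% at most, each over the 50 chosen in the same way on the other 2 mutants. For these probe sets the values argue against replicate 2 as the only source. The interval resamples probe sets within 1 array, so an effect of that array cannot be told from one of the group. Unlike the share, COR15A (147.2 in replicate 1, 204.4 in replicate 2) and LTI30 (142.4 and 216.5) were higher in replicate 2, while AT1G57590 (88 and 71.2) was lower there. Without replicate 2 the change of LTI30 was 1.00 in place of 1.28. Cold-treated RNA in the control samples remains possible: over the 50 probe sets chosen on sf2 and sf6 the median share in sf3 control was 4.14% (bootstrap interval 2.46 to 6.58), near COR15A (4.1%) and LTI30 (3.83%), and over those chosen on the other 2 mutants it was 0.462% in sf6 control and 0.119% in sf2 control. RNA of the 24 h cold sf3 plants mixed in at the COR15A share (3.15% and 5.04%) for every gene is argued against, because 15 of 38 probe sets with a low control level lay more than 2 residual SD below the predicted level and 1 as far above (7 below at 0.5 of that share), and AT1G51090 stood at 19.1 where 56.5 was predicted. An admixture of another profile, a brief chill before harvest and an effect of the sf3 genotype stay open, the last 2 untested.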

How the results depend on the processing

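The comparison with the other mutants was chosen after the results were seen. Of 226 results on named genes under 3391 alternatives, 3027 kept direction and side of the threshold, 364 lost the call and 0 changed direction, and of 974 that left out 1 array 178 lost it. The genes were named for large changes or small adjusted p values in these same data, so a kept direction was largely set by that choice. A lone array left in a group was assumed to vary like the other groups. The cause was not tested where a setting moved a count, unless fewer probe sets or arrays were used. With at least a 2-fold change, the counts were 2064, 1845, 1825 and 1642 for cold in wt, sf6, sf3 and sf2, 218 and 123 for drought in wt and sf6, 13 and 7 for sf3 and sf2 control, and 1156, 1815 and 2149 for 03f against 00f, 24f against 00f and 24f against 03f. With arrayWeights, which weight whole groups here because each has 2 arrays, drought gave 2686 in wt and 1520 in sf6, the sf6, sf3 and sf2 controls 171, 13 and 84, the sf3 difference of cold response 1 and the difference of drought response 3. With only the compared groups, drought in sf6 gave 1387, the sf6, sf3 and sf2 controls 11, 3 and 0, and the differences of cold response in sf6, sf3 and sf2 0, 1 and 8. Without a filter on dim probe sets the controls gave 2, 13 and 3 and the differences 0, 4 and 8. The limma counts of 0 stand beside 1576 (sf2 control) and 1867 (sf6 difference) below an unadjusted p of 0.05 with all groups and the filter. A pseudocount of 64 gave 31 for sf2 control, 4 for the sf3 difference and 1.46 for the raised set in sf6, and a pseudocount of 1 gave 1.62 and -1.61 for the raised and lowered sets in sf6. The 50th percentile filter gave 3 for the sf3 difference, and median scaling 35 for the sf2 difference. Without the 2 repeat1 arrays, drought gave 562 in wt and 233 in sf6, the controls 78, 4 and 59, and the sf6 and sf3 differences 29 and 1; this setting leaves the comparisons of 00f, 03f and 24f as they are and was not run for them. Against the other mutants, sf3 control gave 235 and sf2 control 1, and the sf6 and sf2 differences 0 and 0. Of all list tests 105 were called by camera, 13 with an estimated correlation and 159 by fry.

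The replicate numbers were not taken as pairs: deviations of same-numbered arrays correlated at -0.24 to 0.24 over 45 pairs of groups, and at 0.10 to 0.20 over the 3 pairs of 00f, 03f and 24f. With the replicate block the sf3 difference of cold response gave 2, and no other count moved by over 1.5 times.

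Leaving out 1 array in turn gave 6493 to 7010 for cold in wt, 6015 to 6964 in sf6, 5956 to 6631 in sf3 and 5711 to 5841 in sf2, 581 to 883 for drought in wt and 140 to 226 in sf6. The sf6, sf3 and sf2 controls gave 1 to 107, 5 to 50 and 0 to 91, the differences of cold response 0 to 54, 1 to 19 and 3 to 54, and the difference of drought response 0 to 1 (1 without wt drought replicate 1). The highest counts of the sf6 and sf2 comparisons came without wt control replicate 1, and those of sf3 without sf3 control replicate 1. The lowest came without wt control replicate 2 (sf6 control), wt control replicate 1 (both sf3 comparisons), sf2 control replicate 2 (sf2 control), sf6 control replicate 2 (sf6 difference) and sf2 cold replicate 1 (sf2 difference). For 03f against 00f it was 3100 to 3938, for 24f against 00f 5718 to 6312 and for 24f against 03f 5805 to 6926. The raised set gave 1.49 to 1.64 in wt and 1.52 to 1.59 in sf6, the lowered set -1.71 to -1.57 and -1.57 to -1.48, and the list tests 98 to 112 calls. Changes of dim genes are understated by the added 16.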

Other observations

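The genes and lists below were chosen after their results were seen. The photosynthesis and ribosome groups described for wt moved in the cold in the mutants too. Of 23 nuclear photosynthesis genes 15 fell in sf6 (median -0.54, camera adjusted p = 0.000339, adjusted p = 0.429 with an estimated correlation), 14 in sf3 (median -0.46, camera adjusted p = 7.47e-05, adjusted p = 0.386 with an estimated correlation) and 21 in sf2 (median -0.52, camera adjusted p = 1.67e-06, adjusted p = 0.27 with an estimated correlation). Of 17 RNA polymerase and ribosome biogenesis genes 13 rose in sf6 (median 0.58, adjusted p = 0.0762 with an estimated correlation), 14 in sf3 (median 0.57, adjusted p = 0.0872 with an estimated correlation) and 14 in sf2 (median 0.74, adjusted p = 0.0837 with an estimated correlation). STZ, which led the response to drying, rose in the cold in wt (1.14), sf6 (1.81) and sf2 (0.83), and was at 0.34 in sf3 (adjusted p = 0.275), and the difference between sf3 and wt did not pass (-0.80, adjusted p = 0.701). STZ was higher in 03f than in 00f by 2.45 and lower in 24f than in 03f (-2.69).

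The probe set 261639_at, listed without a gene, stood at 602.4 in wt control and 656.2 in sf2 control, but at 145.9 in sf6 control and 95 in sf3 control. In the cold it was at 572.8 in wt, 565.3 in sf2, 133.8 in sf6 and 136.2 in sf3, after drying at 485.5 in wt and 206.3 in sf6, and between 422.4 and 455.2 in 00f, 03f and 24f. PYK10, at 1619.4 in wt control, was at 22.2, 26.3 and 109.8 in 00f, 03f and 24f.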
